A study of Macaca mulatta with 22 samples.

How the data were processed

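m6A was mapped by immunoprecipitation and stranded sequencing of fragmented total RNA from the prefrontal cortex of 11 rhesus macaques, per the labels' protocols, with an input library beside each immunoprecipitated one. Each of the 11 immunoprecipitated samples has a table of annotated peaks. The 11 input samples carry no table of their own and were not analysed here, so no RNA level of any gene enters the comparisons. The submitters' processing notes name Trim Galore 0.5.0, cutadapt, HISAT2 2.1.0, StringTie and the rheMac8 assembly. The peak caller, and whether each animal's input served as its background, are not given in the sources used here. There is 1 list per animal, and no list is marked as pooled.

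Each row of the deposited tables is a peak with its position, exonic blocks, gene, a p-value, a log10 p-value and a log10 false discovery rate given as negative scores, a fold enrichment (a ratio) and an annotation class, per the file headers. The p-value, both scores and the fold enrichment are the authors' own for each peak. In the files every p-value was at most 0.001, every false discovery rate at most 0.0468 and every fold enrichment at least 2.06. Peak starts count from 0, since 190 starts lay 1 bp below the annotated gene start and 5 on it, so 1 was added to each printed start. Read counts are not part of the tables: the depth is unknown, and no interval for counting error was computed. The precision rests on the number of animals.

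A gene had a peak in an animal if the list placed at least 1 peak in it, by the gene in which the peak was called. In 520 peaks (5.16%) the annotation column named another gene. Ensembl gene identifiers were matched to symbols without their versions: 3235 of 3671 through the supplied table of gene names and 251 through the peak tables, and 185 stayed without a symbol. Regions were built by joining peaks of all animals whose exonic blocks overlapped by at least 1 bp on the same strand. Printed regions span from the first to the last base and include introns between blocks. Position in a gene was that of the peak's midpoint between the annotated gene's ends, for peaks whose caller gene and annotated gene agreed. Exon numbers are not printed, because they rise with the genomic coordinate in all 376 minus-strand and all 268 plus-strand transcripts with at least 2 numbered exons, where tested.

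Groups followed the labels' treatment, and sex and animal names came from the labels and the series' design text. Each label names a separate animal. Numbers of peaks and genes were compared on the log2 scale, and shares as percentages, with two-sided exact permutation tests over all 462 splits into 6 and 5 animals (smallest p = 0.00216). Intervals of 95% are the shifts that the exact test did not reject at 0.05. Males (2 against 2) and females (4 against 3) were also tested apart, and the sex difference by 150 relabellings of sex within treatment. Genes and regions present in 2 to 9 animals were tested with Fisher's exact test and Benjamini-Hochberg adjustment. Similarity was the mean Jaccard index within groups minus that between groups, with a one-sided exact permutation test. For 17 fixed gene lists the number of members with a peak was divided by the animal's genes with a peak and tested exactly, with adjustment over the lists. A symbol with more than 1 gene identifier counted once in an animal.

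Named genes followed a rule set before the data were examined, as were the tests, the gene lists and most of the alternatives. It takes up to 10 genes in each direction by Fisher's p, then by the difference in the share of animals, then by the median percentile of enrichment within a list, then by symbol. It also takes the 10 genes present in all 11 animals with the highest such percentile, genes without a symbol left out throughout, up to 4 members of each list with the largest difference in share of animals (ties by symbol), and each m6A machinery member with a peak. Some list members that the rule takes are not reported here.

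The alternatives were a stricter p-value of at most 1e-05 per peak, autosomes only, exonic peaks only, lists cut to equal length, and no filter on the number of animals. The cut to equal length kept the peaks with the lowest log10 p-values, ties ordered by enrichment. Others were strata by sex and by naming style, the replicate number as a block, and an odds factor per animal for list length (a Rasch model). Regions by 50% reciprocal overlap, other similarity measures, list members as numbers, and leaving out each animal completed the set. Chosen after seeing the data were the gene of the annotation column, leaving out C1 and C3 together, the plus strand alone, and the share of peaks beyond 80% of the gene. The tests were tested on simulated lists with 1486 genes under test, or 1485 in the setting of 80% against 10% of animals. With 100 genes in each direction made present in 98% against 2% of animals, Fisher's test recovered 88 and 82 at an adjusted p under 0.05, and with 80% against 10% it recovered 0 and 0. The first recovery rested on many genes changing together, and a lone gene could not have passed. With no change but list length, 100 simulated data sets gave on average 20.2 genes more often after sevoflurane and 0.13 more often in controls at an unadjusted p under 0.05. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.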

Results

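m6A-seq enriches RNA fragments that carry N6-methyladenosine (m6A), the most common internal modification of mRNA, with an antibody, and reports the enriched stretches as peaks. It was applied to the prefrontal cortex of infant rhesus macaques (Macaca mulatta) at postnatal day 35. Sevoflurane is an inhaled general anaesthetic that potentiates GABA type A receptors. Treated animals had inhaled about 2.5 to 3% of it for 4 h on about postnatal days 7, 21 and 35. The 11 peak lists, 1 per animal, came from 6 control animals (males A and B, females C, C1, C2 and C3) and 5 sevoflurane animals (males D and S1, females F, S2 and S3). They held 10069 peaks in 3671 genes. No read totals accompany the peaks, so the depth of each library is unknown. The comparison addressed is whether repeated exposure is followed by a different set of transcripts with m6A peaks, overall and in each sex. RNA levels were not compared, so a gained or lost peak need not be a change in methylation.

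Of the 3671 genes, 81 had a peak in all 11 animals and 2053 had one in a single animal. Mitochondrially encoded mRNAs stood high among the shared genes when these were ranked by the authors' enrichment of their strongest peak within each list. ND2 and ND6, subunits of respiratory complex I, stood at median percentiles of 99.7 and 99.7, and COX1, the catalytic subunit of cytochrome c oxidase, at 99.3. ND5, COX2 and ND1 followed at 98.8, 98.7 and 98.1. Among nuclear genes, CA11, a carbonic anhydrase-related protein, reached 99.1, and SERPINI1, the axonal protease inhibitor neuroserpin, 98.9. VGF, a secreted neuropeptide precursor, and ZBTB47, a zinc finger gene, both reached 98.8. The shared CA11 region lay on chromosome 19 from 44012833 to 44014520 (minus strand, rheMac8 assembly), and the VGF region on chromosome 3 from 126569040 to 126569668 (minus strand). Each was present in 6 of 6 control and 5 of 5 sevoflurane animals. The enrichment values are the authors' own for each peak and rank genes only within a list.

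Peak lists were longer after sevoflurane. Control animals had 664 ± 282 peaks (SD, n = 6) and sevoflurane animals 1217 ± 295 (SD, n = 5). The ratio of geometric means was 1.90, with a 95% interval of 1.23 to 2.81 from inversion of the exact test. On the log2 scale the difference was 0.93 (two-sided exact permutation test over 462 splits, p = 0.0152). Genes with a peak went the same way, from 601 ± 235 (SD, n = 6) to 1043 ± 222 (SD, n = 5), a ratio of 1.80 with a 95% interval of 1.19 to 2.60 (exact permutation p = 0.0152). The control animal C3, with 1210 peaks, lay among the sevoflurane animals, and the other control lists held 452 to 703 peaks. The labels use single-letter names for 5 animals and numbered names for 6. Within the single-letter animals the log2 difference was 1.11 (3 against 2 animals, exact permutation p = 0.10, the smallest possible). Within the numbered animals it was 0.73 (3 against 3 animals, exact permutation p = 0.20).

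**Figure D1:**
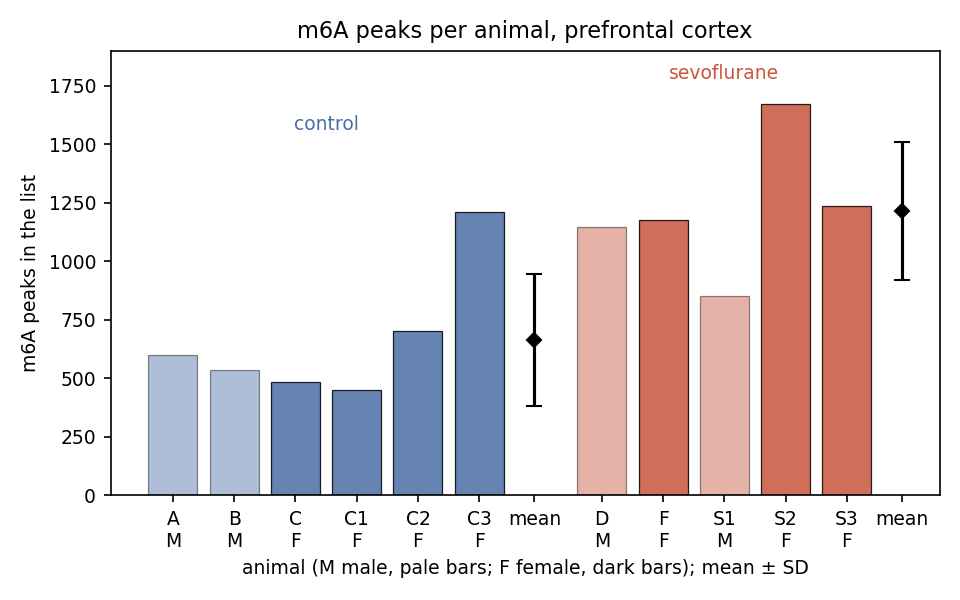
Number of m6A peaks in each animal's list (bars), with the group mean and SD (diamonds). Animals are on the horizontal axis, pale bars are males and dark bars females; the 5 sevoflurane animals have 852 to 1673 peaks, and the controls have 452 to 703 apart from C3 with 1210.

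The difference went the same way in both sexes. Sevoflurane males had 999 ± 208 peaks (SD, n = 2) and control males 568 ± 46.7 (SD, n = 2), a log2 difference of 0.80 (exact permutation p = 0.33, the smallest possible). Sevoflurane females had 1362 ± 271 peaks (SD, n = 3) and control females 712 ± 350 (SD, n = 4), a log2 difference of 1.04 (exact permutation p = 0.0857). The female difference minus the male difference was 0.23 on the log2 scale (two-sided exact permutation of sex within treatment, p = 0.68).

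The annotation classes of peaks and their position along the gene's span, introns included, did not differ detectably between the groups. Every peak carried the authors' class exon, 3' UTR or 5' UTR. The 3' UTR class held 19.5 ± 2.46% of peaks in controls (SD, n = 6) and 19.9 ± 1.85% after sevoflurane (SD, n = 5). That difference of 0.356 percentage points had a 95% interval of -2.55 to 3.45 (exact permutation p = 0.779, adjusted p = 0.779 over 3 classes). The 5' UTR class held 11.6% and 12.0% (exact permutation p = 0.729), and other exons 68.9% and 68.1% (exact permutation p = 0.602). The class depended on the strand of the gene. On the plus strand 25.5% of peaks were in the 3' UTR class, at a median of 95% of the way from the 5' to the 3' end of the gene. On the minus strand 13.4% were, at a median of 19.2%, and 5' UTR peaks there lay at a median of 87.6%. The UTR classes of minus-strand genes therefore sat at the opposite end of the gene, and they are not given for named genes below. The exon class held 81.6% of minus-strand peaks and 55.9% of plus-strand peaks. On the plus strand alone, the 3' UTR share was 26.3 ± 3.43% in controls (SD, n = 6) and 25.2 ± 2.45% after sevoflurane (SD, n = 5; exact permutation p = 0.552). On the minus strand the 3' UTR class held 12.7% in controls and 14.3% after sevoflurane (exact permutation p = 0.141). The 5' UTR class there held 6.05% and 4.37% (exact permutation p = 0.0606). By position in the gene on both strands, 36.7 ± 2.12% of control peaks (SD, n = 6) and 37.8 ± 1.79% of sevoflurane peaks (SD, n = 5) lay beyond 80% of its span (exact permutation p = 0.377).

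**Figure D2:**
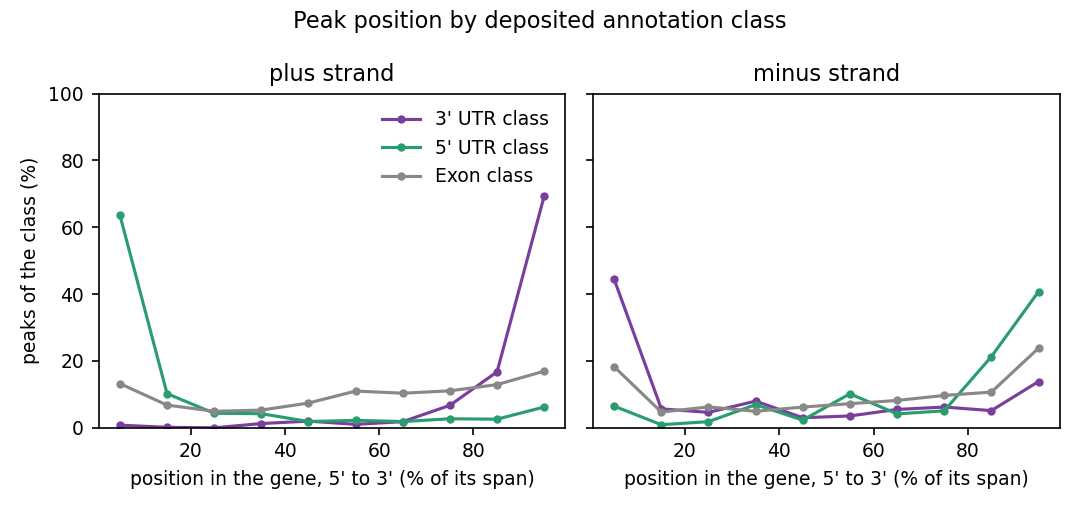
Share of peaks of each deposited class (vertical axis, percent) by position along the gene from the 5' to the 3' end (horizontal axis, percent of the gene's span, bins of 10), for plus-strand genes (left) and minus-strand genes (right), all 11 animals. On the plus strand 69.4% of 3' UTR peaks lie in the last bin; on the minus strand 44.4% lie in the first bin.

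N4BP3, DNMT3A, DCTN3 and DLG3 had peaks in 5 of 5 sevoflurane animals and in 0 of 6 controls (Fisher's exact p = 0.00216 for each, the smallest possible). DNMT3A is a de novo DNA methyltransferase, DLG3 encodes the postsynaptic scaffold SAP102 that binds NMDA receptors, DCTN3 is a dynactin subunit, and N4BP3 is a NEDD4-binding protein. Another 7 genes had peaks in 5 of 5 sevoflurane animals and 1 of 6 controls (Fisher's exact p = 0.0152). The rule for named genes takes 6 of these. They were DDX54, a DEAD-box RNA helicase, PLXNA1, a semaphorin co-receptor, KDM4B, a histone demethylase, MEF2D, a neuronal transcription factor, CPLX3, a complexin, and ABI2, an Abl interactor. Their commonest region was in 5 sevoflurane animals for DDX54, KDM4B and CPLX3, in 4 for PLXNA1 and in 3 for MEF2D. For ABI2, which had 5 regions, it was in 2. None of these genes passed the adjustment over 1486 tested genes, the smallest adjusted p being 0.606. With 0.00216 as the smallest possible p, a gene could pass only if many others reached that p too, and only 4 genes did. The adjusted p therefore decides nothing about single genes. In all, 27 genes had a peak more often after sevoflurane at an unadjusted Fisher's exact p under 0.05 and 0 more often in controls, with 0 at an adjusted p under 0.05 in either direction. The DNMT3A region lay on chromosome 13 between 25521333 and 25546388 (rheMac8, minus strand, exons with the introns between them), and all 5 sevoflurane animals had it. The DLG3 region lay in the 3' UTR, on chromosome X from 65288717 to 65288897 (plus strand), and 4 sevoflurane animals had it. The N4BP3 region, in the 3' UTR on chromosome 6 from 176606589 to 176606769 (plus strand), was found in 3 of them. That of DCTN3, on chromosome 15 from 49647141 to 49649695 (plus strand, 5' UTR and exon), was in all 5. Within their lists these peaks ranked from low to middling: DLG3 stood at a median percentile of 12.4 by enrichment, DCTN3 at 35.1, DNMT3A at 46.6 and N4BP3 at 68.8.

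When each list was reduced to the 452 peaks with the smallest p-values, the length of the shortest list, the count fell from 27 to 4. Enrichment served only to order ties in this cut. DCTN3 and DDX54 were then found in 4 of 5 sevoflurane animals and 0 of 6 controls, and CHD5 and CRYZ in 5 and 1 (Fisher's exact p = 0.0152 for each). Of these 4 genes CRYZ was not among the 27. DNMT3A was found in 2 and 0, and DLG3 and N4BP3 in 0 and 0. PLXNA1 turned to 0 sevoflurane animals against 1 control. An exact test with an odds factor per animal for list length gave 4 genes after sevoflurane (DCTN3, DLG3, DNMT3A and N4BP3, each exact p = 0.0177) and 14 in controls, with 0 at an adjusted p under 0.05. For simulated lists that differed only in length this test gave on average 2 genes after sevoflurane (0 to 6) and 17.1 in controls (8 to 26). With 100 simulated genes present in 98% of sevoflurane and 2% of control animals it recovered 88 at an unadjusted p under 0.05 and 0 at an adjusted p under 0.05. After adjustment it thus had little chance to call a gene in that direction. The stricter peak threshold gave 10 genes after sevoflurane. Of the genes named above, 7 were then no longer under 0.05: N4BP3 and DLG3 (Fisher's exact p = 0.0606), PLXNA1, KDM4B and MEF2D (Fisher's exact p = 0.0801), CPLX3 (Fisher's exact p = 0.242) and ABI2 (Fisher's exact p = 0.545). The count was 59 without C3, 55 without D, 56 without F, 85 without S1, 46 without S2 and 69 without S3. Whichever animal was left out, of either group, the count rose, to between 31 and 85. Group sizes alone change which counts of animals reach an unadjusted p under 0.05, so these counts do not show the weight of single animals.

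In the other direction, AKAP9, a kinase-anchoring protein of the Golgi and centrosome, had a peak in 4 of 6 controls and 0 of 5 sevoflurane animals (Fisher's exact p = 0.0606). Its commonest region, on chromosome 3 from 101830130 to 101830947 (minus strand), was in 2 controls. Without B or without C1 its Fisher's exact p was 0.0476, and the number of genes more often in controls at an unadjusted p under 0.05 was 1. FMR1, which encodes the RNA-binding protein lost in fragile X syndrome, had a peak in 3 of 6 controls and 0 of 5 treated animals (Fisher's exact p = 0.182). Its single region lay in exons on chromosome X from 141645453 to 141648476 (plus strand). GOLGA4, MYO5C, FNBP1L, RANBP2, NIN, CNN3, PTPRZ1 and PGM2L1 showed the same 3 against 0 by gene. The commonest region was in 3 controls for FMR1 and PGM2L1, and in 2 for MYO5C, FNBP1L and CNN3. For GOLGA4, RANBP2, NIN and PTPRZ1 it was in 1, so no region of these was shared between controls. PTPRZ1 is a receptor phosphatase of glia and their precursors, MYO5C an unconventional myosin, RANBP2 a nuclear pore protein, and NIN the centrosomal protein ninein. In the test with an odds factor for list length AKAP9 had an exact p of 0.00506 and the other 9 an exact p of 0.0241, all with an adjusted p of 1. It gave 14 genes in this direction, within the 8 to 26 (mean 17.1) of simulated lists that differed only in length.

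**Figure D3:**
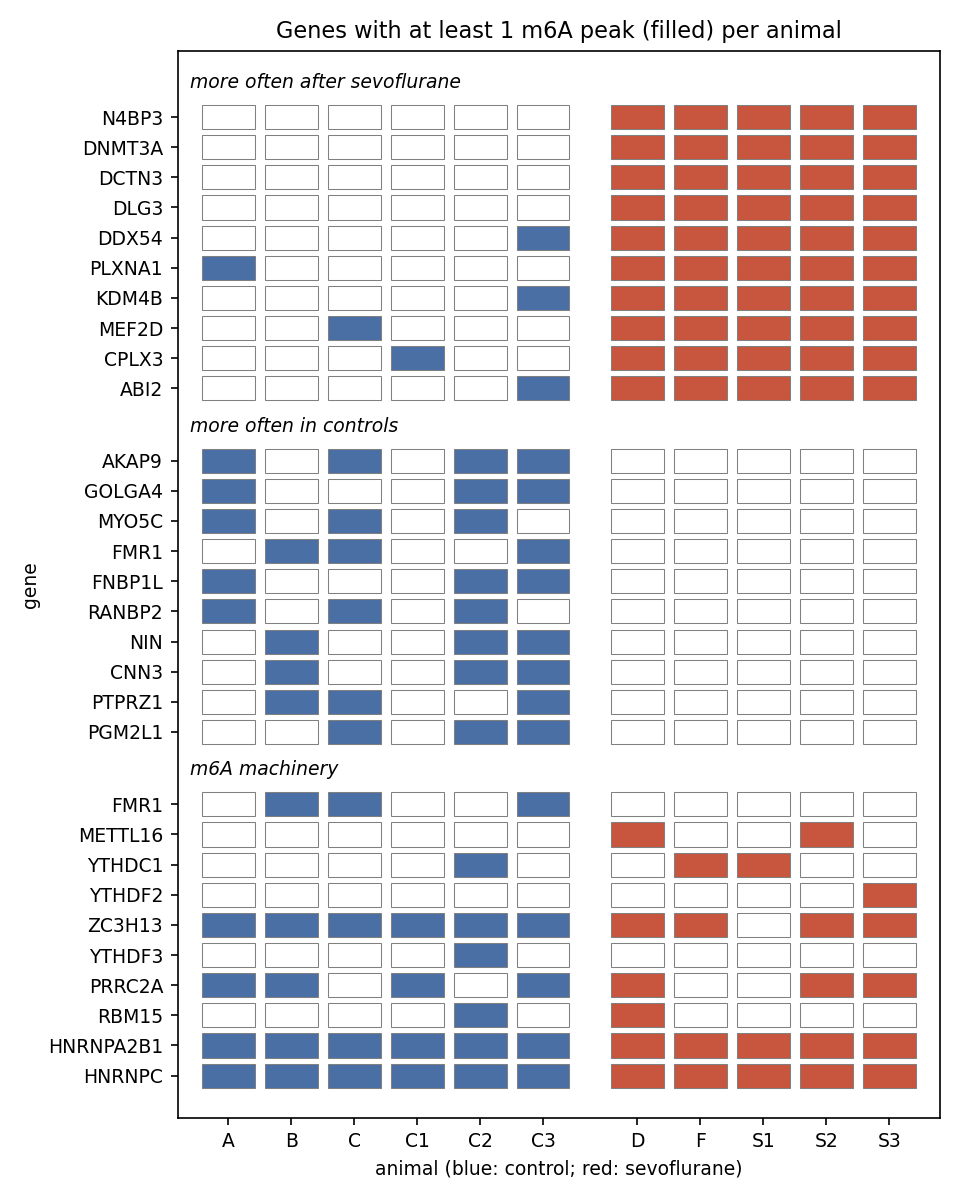
Presence of at least 1 m6A peak (filled cell) for each gene (rows) in each animal (columns; blue controls, red sevoflurane animals), for the 10 genes ranked first in each direction and the 10 members of the m6A machinery list with a peak. DNMT3A, DLG3, DCTN3 and N4BP3 are filled in 5 of 5 sevoflurane animals and 0 of 6 controls; HNRNPA2B1 and HNRNPC are filled in all 11 animals.

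Merging overlapping peaks on the same strand gave 5155 regions, of which 1265 were tested. There were 19 regions more often present after sevoflurane at an unadjusted Fisher's exact p under 0.05 and 0 more often in controls, and none passed the adjustment (smallest adjusted p = 0.610). As for genes, a region could pass only if many others reached the smallest possible p too. With an odds factor for list length the counts were 2 and 9, and with lists of equal length 4 and 0. Without C3, D, F, S1, S2 or S3 the count after sevoflurane was 43, 38, 42, 68, 32 or 62. These counts, too, move with group size alone.

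By the Jaccard index, gene sets were slightly more alike within groups than between them, mostly through the sevoflurane animals. This was not so by the overlap coefficient or with lists of equal length. The mean Jaccard index of gene sets was 0.244 within groups and 0.221 between them, a difference of 0.0230 (one-sided exact permutation p = 0.0260). Pairs of sevoflurane animals averaged 0.268 and pairs of controls 0.227. The overlap coefficient, which divides by the shorter list, gave a difference of -0.0470 (one-sided exact permutation p = 0.983), and lists of equal length gave -0.00247 (exact permutation p = 0.558). The overlap coefficient can be high where a short list meets a long one, mostly between groups. Its highest value, 0.671, was that of C and S2, so its negative difference is not free of list length. The exact permutation p of the Jaccard difference was 0.0619 without D, 0.0810 without F, 0.0524 without S1, 0.105 without S2 and 0.0667 without S3. No pair of animals had a Jaccard index above 0.363, so no list repeated another.

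Transcripts of the m6A machinery, writers and readers of the mark among them, carried peaks in both groups. Of the 24 members of this list, 10 had a peak in any animal, 4.67 ± 0.816 per control animal (SD, n = 6) and 4.60 ± 1.14 per sevoflurane animal (SD, n = 5; exact permutation p = 1). HNRNPA2B1 and HNRNPC, nuclear RNA-binding proteins, had peaks in all 11 animals, and ZC3H13, a subunit of the methyltransferase complex, in 6 of 6 controls and 4 of 5 sevoflurane animals. PRRC2A had a peak in 4 controls and 3 sevoflurane animals, YTHDC1 in 1 and 2, METTL16 in 0 and 2, RBM15 in 1 and 1, YTHDF2 in 0 and 1, YTHDF3 in 1 and 0, and FMR1 in 3 and 0. As a share of all genes with a peak the list was lower after sevoflurane, 0.444 ± 0.0934% (SD, n = 5) against 0.834 ± 0.203% (SD, n = 6; exact permutation p = 0.00866, adjusted p = 0.0736 over 17 lists). With members in near-equal number, that share fell because the total of genes with a peak rose from 601 to 1043. With lists of equal length the difference in share was -0.171 percentage points (exact permutation p = 0.0823).

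Axon guidance genes had the smallest p by number of members among the fixed lists. Of 22 members 10 had a peak, on average 0.5 per control animal and 3.4 per sevoflurane animal (exact permutation p = 0.0108, adjusted p = 0.129). Their share was 0.0616 ± 0.0955% in controls (SD, n = 6) and 0.346 ± 0.211% after sevoflurane (SD, n = 5; exact permutation p = 0.00866, adjusted p = 0.0736). PLXNA1 had a peak in 1 control and 5 sevoflurane animals, the ephrin receptor EPHB2 and PLXNA2 each in 0 and 3, and DSCAM in 0 and 2. With lists of equal length the share difference was 0.157 percentage points (exact permutation p = 0.152). Immediate early genes, which neuronal activity induces, had no peak in any control and 0.80 members per sevoflurane animal (exact permutation p = 0.0152 for the share, adjusted p = 0.0859). EGR1, FOSL2, JUNB and NR4A2 each had a peak in 1 sevoflurane animal, and 0 members were left at the stricter threshold. None of the 17 lists passed the adjustment by share or by number of members. At an unadjusted exact permutation p under 0.05 there were 3 lists by share, 5 by number of members and 0 by share with lists of equal length.

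Chromatin regulators had peaks in 18 of 22 members, 2.17 ± 2.14 per control animal (SD, n = 6) and 6.4 ± 3.44 per sevoflurane animal (SD, n = 5; exact permutation p = 0.0346, adjusted p = 0.147). The histone methyltransferase genes KMT2A and KMT2D each had a peak in 1 control and 4 sevoflurane animals, ASXL1 in 0 and 3, and BPTF in 2 and 4. Their share of genes with a peak, 0.307% in controls and 0.603% after sevoflurane, gave an exact permutation p of 0.0866, from 0.0476 without C3 or without F to 0.181 without S3, and with lists of equal length the share difference turned to -0.0381 percentage points (exact permutation p = 0.939). PI3K-mTOR and Wnt genes numbered 1 per control and 2.6 per sevoflurane animal (exact permutation p = 0.0325, adjusted p = 0.147), with RPTOR in 1 and 3 animals and AKT1, AKT2 and IRS1 each in 0 and 1. Their share differed by 0.102 percentage points (exact permutation p = 0.186), and by 0.0278 with lists of equal length (exact permutation p = 0.784). Ion channel genes numbered 1.83 and 4 (exact permutation p = 0.0498, adjusted p = 0.169), with the calcium channel genes CACNA1B and CACNA1C and the sodium channel gene SCN3A each in 0 controls and 2 sevoflurane animals, and CACNA1E in 1 and 2. Their share gave an exact permutation p of 0.115, from 0.00794 without C3 to 0.210 without S1, and with lists of equal length the share difference turned to -0.0372 percentage points (exact permutation p = 0.948).

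Synaptic lists did not pass the tests as groups. Postsynaptic scaffold and adhesion genes had peaks in 16 of 24 members, 6.33 per control and 7.80 per sevoflurane animal (exact permutation p = 0.229). Their share was lower by a difference of -0.310 percentage points (exact permutation p = 0.0909). It was -0.453 without S1 (exact permutation p = 0.00952) and -0.247 without S3 (exact permutation p = 0.167), on autosomes alone -0.475 (exact permutation p = 0.0216), and with lists of equal length it turned to 0.106 (exact permutation p = 0.621). Adjusted over the list alone, DLG3 passed (Fisher's exact test, adjusted p = 0.0152), against 0 members adjusted over all genes. DLG3 was in 0 and 0 animals with lists of equal length, and had a Fisher's exact p of 0.0606 at the stricter threshold. DLGAP3 had a peak in 0 controls and 3 sevoflurane animals, IQSEC2 in 1 and 2, and DLGAP1 in 5 and 3. In the other 16 lists, 0 members passed adjusted over the list alone. Presynaptic vesicle genes had peaks in 14 of 22 members, 4.17 and 5.80 per animal (exact permutation p = 0.232), with RIMS1 in 0 and 3, UNC13A in 1 and 3, PCLO in 2 and 3, and the calcium sensor SYT1 in 2 and 0. Their share went the other way, by -0.179 percentage points (exact permutation p = 0.182), and with lists of equal length by 0.266 (exact permutation p = 0.290). Glutamate receptor genes had peaks in 8 of 24 members, 0.833 and 1.60 per animal (exact permutation p = 0.314). GRIK5 was in 0 and 2 animals, GRIN1 in 0 and 1, GRM2 in 1 and 2, and GRIA1 in 2 and 0. The share differed by 0.0634 percentage points (exact permutation p = 0.483). GABA signalling genes, which include the receptors on which sevoflurane acts, had peaks in 4 of 20 members, 1.67 and 2.00 per animal (exact permutation p = 0.688). GABBR1 had a peak in 5 controls and 5 sevoflurane animals, the vesicular transporter SLC32A1 in 3 and 2, GABRD in 1 and 2, and GABRA4 in 1 and 1. The GABA share differed by -0.113 percentage points (exact permutation p = 0.275), and with lists of equal length by 0.0236 (exact permutation p = 0.736).

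Cell type markers and ribosomal protein genes gave no difference that passed a test with all animals. Neuron markers had peaks in 5 of 19 members, 1.67 per control and 2.20 per sevoflurane animal (exact permutation p = 0.803), with RBFOX3 in 4 and 3 animals and CUX2, NEFH and NEFL each in 0 and 1. Their share went the other way, with a difference of -0.0898 percentage points (exact permutation p = 0.149). It was -0.133 without S2 (exact permutation p = 0.0381) and -0.0627 without S3 (exact permutation p = 0.290), and with lists of equal length it turned to 0.0849 (exact permutation p = 0.652). Oligodendrocyte and myelin genes had 7 of 19, 0.833 and 1.80 per animal (exact permutation p = 0.184). PDGFRA, a marker of oligodendrocyte precursors, had a peak in 0 controls and 3 sevoflurane animals, on chromosome 5 from 81392313 to 81392492 (minus strand), and ENPP2, MBP and OLIG2 each in 0 and 1. The share differed by 0.0419 percentage points (exact permutation p = 0.658), and with lists of equal length by -0.0137 (exact permutation p = 0.913). Astrocyte markers had 5 of 14, 1.67 and 2.20 per animal (exact permutation p = 0.273), with APOE and GJA1 each in 0 and 1, and SLC1A3 in 1 and 0. The astrocyte share differed by -0.0770 percentage points (exact permutation p = 0.223), and with lists of equal length by 0.0916 (exact permutation p = 0.387). Vascular markers had 4 of 13, 0.5 and 1 per animal (exact permutation p = 0.610), with COL4A2 in 1 and 3, COL4A1 in 0 and 1, SLC2A1 in 1 and 0, and TEK in 1 and 1, and a share difference of 0.0126 percentage points (exact permutation p = 0.805). Microglia markers had a peak in 1 of 14 members, CX3CR1 in 1 control (exact permutation p = 1). Cell death and stress genes had 2 of 19, among them BAX in 1 sevoflurane animal (exact permutation p = 1). Ribosomal protein genes had 4 of 22, 0.333 and 1.40 per animal (exact permutation p = 0.0801), with RPS14 in 1 and 2, RPS9 in 0 and 1, and RPL7 in 1 and 1. The difference in ribosomal share was 0.0973 percentage points (exact permutation p = 0.145), 0.131 without C (exact permutation p = 0.0476) and 0.0667 without S1 (exact permutation p = 0.286). With lists of equal length it was 0.0650 (exact permutation p = 0.437).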

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

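The tests of naming style (of the lists and of C1), depth, small RNA and strand were chosen after the results were seen, and those of other splits and of list length alone before. Dixon's test for a single outlying animal was run on 50 sets of values within a group, where chance alone marks about 1 in 20, and it marked 6. The marks for C, B and S2 are list shares above 0 in only 1 animal of the group, which the test always marks. The rate of 1 in 20 does not hold for such values.

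The first pattern is the longer lists and the 27 genes more often present after sevoflurane. Naming style as a batch is argued against, since relabelling within styles left a log2 difference of 0.90 (exact permutation p = 0.02). Simulated lists that differed only in length gave 20.2 genes on average, from 11 to 32, a range that holds the observed 27, so list length alone may account for the gene count. Deeper sequencing or better enrichment of the sevoflurane libraries stays open for the lists themselves. Among peaks with p at most 1e-05 the log2 difference was 0.76 (exact permutation p = 0.0130). This was below the 0.93 of all peaks, the direction predicted for either. A gain of weak peaks with the exposure would give the same direction, so the value does not separate them. The median fold enrichment was 5.08 to 6.26 in sevoflurane lists and 5.43 to 7.62 in control lists. No read totals were at hand to separate depth or enrichment from the exposure, whose effect on methylation also stays open. RNA levels did not enter the comparison, so a change in peaks cannot be told apart from a change in RNA level. Among 100 splits of the animals into 6 and 5, 2 gave at least 27 genes, the real one included. The other gave 44 by grouping C3 with D, F, S1 and S2, all animals with long lists. The log2 differences in peaks were 0.928 in the real split and 0.916 in the other. The count thus goes with the difference in list length, and the splits say nothing about the genes apart from it.

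For regions, 3 of 100 splits gave at least 19 more often present in the group of 5, the real split included, and the highest other gave 37. In the direction of controls the real counts were 0 genes and 0 regions, which 100 and 100 of 100 splits matched because no count is under 0, so the splits say nothing there. The highest other counts were 30 and 29.

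The second pattern is the control animal C1, which had 74 peaks annotated to genes shorter than 400 bp, against 17 in the next control. The other 10 animals had 12 to 24. Naming style as a batch is argued against, as the other numbered animals reached at most 24. Of the C1 peaks, 36 lay in snoRNA, U RNA and Y RNA genes, where other lists had 0 to 5, so more small RNA in that library is a candidate explanation. It cannot be told apart from a difference in the tissue sample, since the input library was not analysed here, and no biological explanation was tested.

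The third pattern is that the UTR classes depended on the strand. Exons of minus-strand transcripts read in genomic order by the annotation are consistent with the values: the median 3' UTR peak lay at 19.2% of a minus-strand gene from its 5' end, and exon numbers rose with the coordinate in all 376 minus-strand transcripts tested. A true difference in placement is argued against as the whole source, because 19.0% of minus-strand 3' UTR peaks lay beyond 80% of the gene, against 86.1% on the plus strand. No biological explanation was tested.

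The control animal C3 had 1210 peaks, against 703 in the next control. C3 also had 1050 genes with a peak, against 642 in the next control. In the microglia list, control animal C was the only control with a member, at 0.222% of its genes. In the cell death and stress list, B was the only control with a member, at 0.201%, and S2 the only sevoflurane animal, at 0.0741%.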

How the results depend on the processing

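The longer lists kept their direction and their side of the threshold under every alternative run, with log2 differences of 0.80 to 1.12 in peaks and 0.75 to 1.02 in genes when any 1 animal was left out. No paired animals are described. The correlation of presence between same-numbered animals, after removing group means, was 0.0636 for C1 and S1, 0.0106 for C2 and S2, and -0.0233 for C3 and S3. Differently numbered pairs ran from -0.0754 (C3 and S1) to 0.0518 (C3 and S2), so C1 and S1 stood highest. All values were near 0, and whether the numbers pair animals was not tested. With the replicate block the log2 difference in peaks was 0.90 (exact permutation p = 0.0125, the smallest possible), the counts were 19 genes and 16 regions after sevoflurane, and no result of a comparison changed its call, while PLXNA1, MEF2D and the immediate early list went to an exact p of 0.05. Every peak was exonic, so that filter moved nothing. The unknown depth limits all counts, since a weak peak can be missed in a shallow library.

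The counts of genes and regions depended on list length. They also moved when single animals were left out, but group sizes alone change which counts of animals reach an unadjusted p under 0.05. Genes and regions more often present after sevoflurane numbered 10 and 11 at the stricter threshold, 4 and 4 with lists of equal length, 4 and 2 with an odds factor for list length, and 73 and 57 without C1 and C3 together. In controls they numbered 14 and 9 with the odds factor, where simulated lists that differed only in length gave 17.1 genes (8 to 26), and 3 and 1 without C1 and C3. Leaving out 1 animal gave 31 to 85 genes and 22 to 68 regions after sevoflurane, and 0 to 1 genes and 0 to 0 regions in controls. The similarity difference turned to -0.0470 with the overlap coefficient and to -0.00247 with lists of equal length, and ranged from 0.0145 to 0.0395 when 1 animal was left out, with the call lost without any 1 of the sevoflurane animals. The difference in 3' UTR share turned to -0.178 on autosomes, -0.229 without C1 and C3, and -1.10 on the plus strand, and ranged from -0.323 to 1.01 percentage points when 1 animal was left out. Apart from list length, the cause was not tested.

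With lists of equal length PLXNA1 turned to -16.7 percentage points of animals, and share differences of lists turned to 0.0236 (GABA signalling), 0.106 (postsynaptic), 0.266 (presynaptic), -0.0372 (ion channels), 0.0849 (neuron), -0.0137 (oligodendrocyte), 0.0916 (astrocyte) and -0.0381 (chromatin). Counted as members, differences turned to 0.333 (GABA signalling), 1.47 (postsynaptic), 1.63 (presynaptic), 0.533 (neuron), 0.533 (astrocyte) and 0.0333 (cell death). The vascular difference turned to -0.00318 without C1 and C3 and spanned -0.0200 to 0.0369 when 1 animal was left out, with -0.00323 without C, C1 or C2. The cell death difference spanned -0.0335 to 0.0148, the latter without B.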

Other observations

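The tests of mitochondrial peaks, of genes found in 2 animals and of the X chromosome were chosen after the results were seen, and the first test of genes of 1 group only before. Mitochondrial transcripts carried 16.8 ± 1.94 peaks per control animal (SD, n = 6) and 17.2 ± 2.28 per sevoflurane animal (SD, n = 5) (exact permutation p = 0.879). The mRNAs of COX1, COX2, COX3, CYTB, ND1, ND2, ND4, ND5 and ND6 had a peak in all 11 animals, and those of ATP6 and ND3 in 9. The number of these mRNAs with a peak thus had little room to rise with list length. Whether the number of peaks on them had room to rise was not tested. The peaks of ND1, COX2 and ND6 each merged into 1 region, present in all 11 animals, while ND2 and ND5 had 2 regions and COX1 had 3. ND6, the mRNA encoded on the other strand from the rest, had a median authors' enrichment of 163 over its peaks.

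Genes with a peak in 1 treatment group only numbered 838 in controls and 1650 after sevoflurane, beside 1183 found in both groups. The hypothesis that such genes have peaks near the lower end of their list was tested by rank within each list. The median percentile of their strongest peak was lower than that of shared genes in 11 of 11 animals, on average by -11.4 points (exact sign-flip test, p = 0.000977, the smallest possible), by -10.5 in controls and -12.4 after sevoflurane. It lay near the middle of the lists, at 39.1 to 50.3. Genes of 1 group only were found in 1.23 animals on average and shared genes in 4.88, so this split alone can set the sign, and the test decides nothing. Among genes found in exactly 2 animals the difference was 4.38 points in the other direction. Of 11 animals, 2 were lower (exact sign-flip test, p = 0.117). A lower rank was thus not seen among these genes, but the p-value does not settle the direction. The 2053 genes found in 1 animal belong to 1 group by definition, so no shared genes match them in number of animals. For them the hypothesis stays undecided.

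X-linked peaks made up 4.24 ± 0.502% of the list in controls (SD, n = 6) and 3.16 ± 1.06% after sevoflurane (SD, n = 5; exact permutation p = 0.0325, adjusted p = 0.13 over 4 measures). Without S1, which had 1.41%, the exact permutation p was 0.0810. Among females the shares were 4.31% and 3.79% (exact permutation p = 0.0286, the smallest possible), and among males 4.09% and 2.23% (exact permutation p = 0.333, the smallest possible).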
